A study of Danio rerio with 6 samples.

How the data were processed

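The study sorted osteoblasts, the bone-forming cells, from regenerating scales of zebrafish that carried 2 reporters driven by osterix (sp7) regulatory sequence. One reporter, H2A-mCherry, marks osteoblast nuclei. The other, Venus-hGeminin, carries the degradation signal of geminin, so that it accumulates in cells in S, G2 and M phase. Per the labels' protocols, about 50 scales in 3 rows were plucked from each side of a fish, the regenerating scales were collected on day 4, and 3 to 5 fish were used per sample. The scales were digested with Liberase for 1 h, and live single mCherry-positive cells were sorted by Venus-hGeminin signal. RNA was extracted and a low-input library was made from each sample. The labels give 3 Geminin-negative and 3 Geminin-positive libraries.

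The deposited unit is the raw read count per gene. Per the submitters' processing notes, the tools named are Trim Galore 0.4.1, TopHat2 2.1.1 and featureCounts 1.6.1, with the genome build danRer10. The strand setting, the treatment of reads that map to several places and the annotation release are not given in the sources used here. Without a stated strand, reads from overlapping or antisense genes cannot be told apart. Reads shared by near-identical copies, such as the col1a1 and cd74 pairs, the hsp70 genes and the MFAP4 cluster, may be split between them. The deposited tables also give gene coordinates and a gene length, another measure made by the authors' counting tool, which served here for the length check. The tables hold 34289 Ensembl genes on 25 chromosomes and 0 mitochondrial rows, so the share of mitochondrial reads was not analysed here.

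Gene symbols came from a table of Ensembl identifiers, which gave a symbol for 26790 of the 34289 genes. Current zebrafish symbols were matched through NCBI RefSeq annotation of assembly GRCz12tu. A unique symbol matched 16513 genes, and the base name with the chromosome and a shared neighbour within 10 genes matched another 4079. The table's symbol alone was kept for 6198 genes, which is why some names are in capitals, and 7499 genes had none. No coordinate came from that assembly. Coordinates are those of the deposited tables, in danRer10.

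Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, libraries were scaled by TMM, and the Geminin-positive group was compared with the Geminin-negative group by the robust quasi-likelihood test with Benjamini-Hochberg adjustment and a threshold of 0.05. A positive log2 fold change means a higher level in the Geminin-positive libraries, and its standard error (SE) is the absolute log2 fold change divided by the root of the F statistic. CPM is the count scaled to library size in the usual CPM unit, after TMM scaling, given as mean ± SD. The 28 gene lists and the families of ribosomal proteins and histones were tested with limma 3.58.1, using camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Lists with at least 5 measured members entered the test, which left 29 of the 30. Shares of counts were compared by an exact two-sided permutation test, which with 3 against 3 libraries cannot give a p below 0.1. They are shares of a library's total counts without TMM scaling, so a larger share of 1 class lowers the others. For a gene with 0 counts in a whole group, the fold is a lower bound against a floor of 3 counts over that group. With 1 to 3 counts, the fold has a 95% Poisson interval. Intervals and floors cover counting error only, since the reads carry no molecular identifiers in the sources used here.

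The 28 lists, the 2 families, the tests between the groups, the alternatives listed here and the rule for named genes were fixed before the data were examined. Exceptions, chosen after seeing the data, were a lysosome list, an alternative without leukocyte and osteoclast list members, and tests of abundant leukocyte genes, of swapped libraries and of the gmnn level. The rule named sp7, gmnn, dusp6 and spry4 as checks. It also named the 12 largest increases and 12 largest decreases among called genes with at least 10 CPM in a group, no overlap between groups and a symbol that is not a clone name. Up to 4 members of each list with the smallest p and the 5 genes with the highest mean CPM completed it. Genes named outside it are marked as such.

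Total counts per library ranged from 15854710 to 34472612, and no pair of libraries was a duplicate, since the smallest chi-square per degree of freedom between any 2 was 94.91. The biological coefficient of variation was 1.123. On simulated data with the real means, dispersions and library sizes, 200 of 11734 genes were changed by 4-fold to 32-fold. These 200 were drawn from genes with a mean of at least 10 CPM, so recovery of less abundant genes was not measured. The members of 5 of 20 simulated lists, each of 40 other genes, were also shifted by 1 log2 unit and were not counted as false calls. The test recovered 18% of those changed 4-fold, 62% of those changed 8-fold, 90% of those changed 16-fold and 94% of those changed 32-fold, and 2.92% of its calls were false. In the same simulation of this comparison 35.7% of the DESeq2 calls were false. All 5 of the simulated lists that were shifted were called, and 0 of the others. Genes were simulated independently, so this cannot show how many false list calls arise when members are correlated. In the real data the estimated correlation was as high as 0.586, for the respiratory chain list.

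Alternatives were DESeq2 1.42.0, limma-voom, other scalings, no filter and a stricter filter of at least 5 CPM in 3 libraries. Others were a correction for gene length, the replicate number as a block, a fit without robust dispersion, a threshold of 0.01, each library left out in turn, camera with an estimated correlation, and fry. Leaving out mitochondrial rows changed nothing to test, as there are 0. The labels do not say whether libraries with the same number share fish, and p-values measure the spread between these samples. Calculations outside R used Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.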

Results

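Gene expression was measured by RNA sequencing in osteoblasts of regenerating zebrafish scales, sorted on day 4 after plucking into a Venus-hGeminin-negative and a Venus-hGeminin-positive gate, with 3 libraries each. The comparison was set up to contrast osteoblasts with low and high Erk activity, Erk being the kinase of the MAP kinase cascade. The sample labels call the Geminin-positive libraries high Erk, whereas the series' design text states an inverse relation between the reporter and Erk activity. The groups are therefore named here by their gate, and no direction of Erk activity is taken from the labels. Total counts were 15854710, 34472612 and 17889148 in Geminin-negative replicates 1 to 3 and 16482720, 19087246 and 18345577 in Geminin-positive replicates 1 to 3. Between 11977 and 17875 genes had at least 1 count. On the first principal component, which held 31.3% of the variance, Geminin-negative replicates 1 to 3 had scores of -15.6, -56.6 and -203.4. Geminin-positive replicates 1 to 3 had scores of 72.5, 108.3 and 94.8, so the groups did not overlap on it.

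Genes of G2 phase and mitosis were higher as a list in the Geminin-positive libraries, and the type I collagen genes col1a1a and col1a1b rose. Genes of leukocytes and osteoclasts were lower as lists. Of 12855 genes tested, 78 changed, 16 higher and 62 lower in the Geminin-positive libraries. All 78 changed by at least 1 log2 unit. At an unadjusted p under 0.05 there were 1209 genes, 468 higher and 741 lower. The 2 groups did not overlap in 18.42% of the genes, against 10% by chance. Replicates varied widely: of genes with at least 100 counts in a library, 21.59% in the Geminin-negative group and 12.02% in the Geminin-positive group had 0 counts in another library of the group. The count of changed genes was 32, 22 and 25 without Geminin-negative replicates 1, 2 and 3, and 34 and 40 without Geminin-positive replicates 2 and 3. In these 5 fits 5, 1, 4, 3 and 3 genes were higher, whereas without Geminin-positive replicate 1 there were 25 higher of 96. The count was 626 with DESeq2, of which 194 were higher, and 557 without a filter, of which 156 were higher. There were 39 higher of 97 with limma-voom and 7 higher of 52 with the length correction. With scaling by library size alone it was 185, of which 12 were higher and 173 lower, with the median gene shifted by -0.46.

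**Figure D1:**
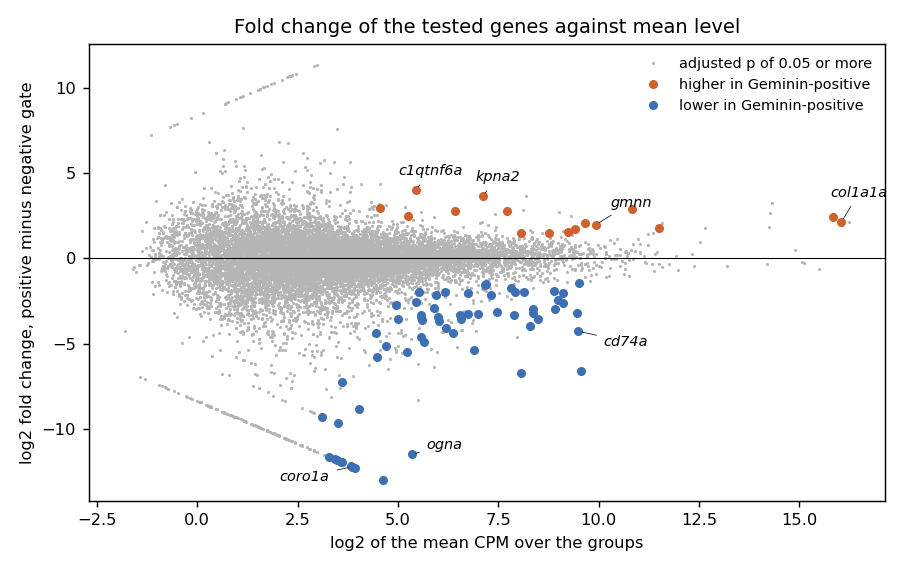
Each point is 1 of the 12855 tested genes, by the log2 of its mean CPM over the groups (horizontal) and its log2 fold change, Geminin-positive minus Geminin-negative (vertical). The 16 genes higher and 62 lower past the adjusted threshold are coloured, and the diagonal rows of points at the edges are genes with 0 counts in a whole group.

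The genes that check the sort behaved as follows. The geminin gene gmnn (ENSDARG00000035957, chromosome 19, 31998028 to 32140417), an inhibitor of replication licensing, rose from 398 ± 30.4 to 1556 ± 66.7 CPM (SD, n = 3 each; log2 fold change 1.97, SE 0.21, edgeR adjusted p = 0.01057). Its row overlaps that of ripor2. The osteoblast transcription factor gene sp7 had 112 ± 34.8 CPM in the Geminin-negative and 200.3 ± 63.3 CPM in the Geminin-positive libraries, a difference that did not pass the test (adjusted p = 0.4642 by edgeR).

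All 38 measured members of the G2/M list had a positive log2 fold change, with a median of 3.02, and camera called the list higher (adjusted p = 4.288e-20). It stayed called with an estimated correlation (adjusted p = 0.04646). Over all genes 1 member, gmnn, passed the test, and adjusted over the list alone 5 did. The median was 5.71 with limma-voom. With the 2 members at 0 counts in a whole group set to their bound, the main median was again 3.02. The topoisomerase gene top2a had 0.119 ± 0.207 CPM against 22.0 ± 8.57 CPM, and the spindle assembly gene tpx2 had 4.52 ± 2.32 against 34.0 ± 17.4 CPM; both passed adjusted over the list alone (adjusted p = 0.01938 by edgeR). The condensin gene ncapd2 had 0 counts in the Geminin-negative libraries and 15.7 ± 10.7 CPM in the others. The G2/M share of all counts was 0.0688% ± 0.0111 against 0.207% ± 0.0281 (exact permutation p = 0.1, the smallest possible). Without gmnn that share was 0.0218% ± 0.00556 against 0.0746% ± 0.0244.

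The S phase list was not called (camera adjusted p = 0.6621), and its share of counts was 0.0627% ± 0.0134 against 0.0548% ± 0.00906 (exact permutation p = 0.5). Of its 31 measured members 16 had a positive log2 fold change, and 1 passed over all genes and adjusted over the list alone. That member, RRM2, a ribonucleotide reductase subunit (ENSDARG00000078069, chromosome 19, 48003903 to 48010821), rose from 11.7 ± 2.76 to 64.3 ± 9.37 CPM (log2 fold change 2.46, SE 0.37, edgeR adjusted p = 0.0321). The replicative helicase gene mcm3 had 30.4 ± 12.3 CPM in the Geminin-negative and 10.6 ± 2.35 CPM in the Geminin-positive libraries (edgeR adjusted p = 0.3332). The list of cell cycle exit genes was not called either (camera adjusted p = 0.6017), with 11 of 18 members positive and 0 passing. Histone genes were called higher (camera adjusted p = 0.03658; adjusted p = 0.2245 with an estimated correlation), with 9 of 13 members positive and 0 passing over all genes or adjusted over the list alone. The call was lost without Geminin-negative replicate 1 (adjusted p = 0.05569), with library size only (0.06561) and with limma-voom (0.3653). It was also lost with the replicate block (camera adjusted p = 0.05637) and with the length correction and block (0.05197). The camera direction turned under the stricter filter (adjusted p = 0.867). Histone genes took 0.0931% ± 0.00912 against 0.0902% ± 0.0561 of counts (exact permutation p = 1).

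Outside the lists, kpna2, an importin of nuclear transport (ENSDARG00000038066, chromosome 3, 25239370 to 25246615), rose from 20.2 ± 3.83 to 256 ± 122 CPM (log2 fold change 3.66, SE 0.43, edgeR adjusted p = 0.01817). The glutathione transferase gene gstr rose from 53.3 ± 10.2 to 370 ± 139 CPM (adjusted p = 0.01977, edgeR). Other increases were those of c1qtnf6a (log2 fold change 4.02), myo18aa (2.93), itgbl1 (2.79) and aebp1b (1.73). Each of these 6 genes lost its call in at least 1 alternative, and the highest adjusted p among them over the alternatives was 0.157, for myo18aa.

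**Figure D2:**
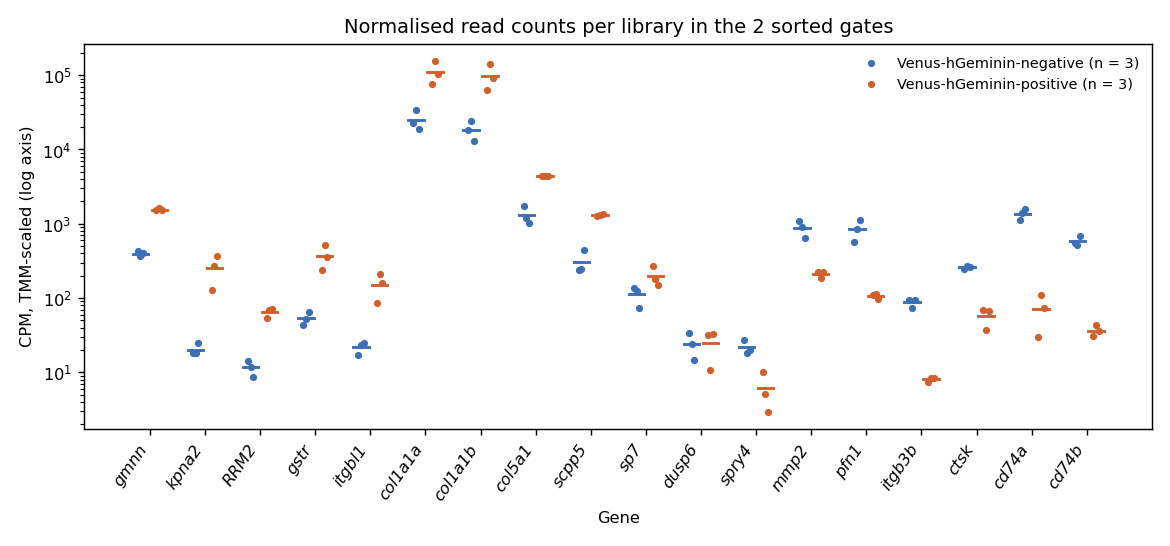
Each point is the TMM-scaled CPM of 1 library (log axis) for 18 named genes, and the horizontal bar is the group mean, with 3 libraries per gate. The gmnn points lie between 365 and 426 CPM in the Geminin-negative libraries and between 1516 and 1633 CPM in the Geminin-positive libraries.

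Bone matrix genes moved in both directions. Of 45 measured members 22 had a positive and 23 a negative log2 fold change, and camera did not call the list (adjusted p = 0.5379). Over all genes 4 members rose and 2 fell, and adjusted over the list alone 14 rose and 9 fell. The type I collagen gene col1a1a (ENSDARG00000012405, chromosome 3, 23090499 to 23108910) rose from 25143 ± 7806 to 110190 ± 39330 CPM (log2 fold change 2.13, SE 0.35, edgeR adjusted p = 0.04627), and its copy col1a1b had a log2 fold change of 2.41 (adjusted p = 0.03967, edgeR). The fibrillar collagen gene col5a1 rose from 1316 ± 383 to 4434 ± 19.2 CPM, and scpp5, a secretory calcium-binding phosphoprotein gene, rose from 309.9 ± 116 to 1304 ± 46.4 CPM. The matrix protease gene mmp2 fell from 883 ± 226 to 212 ± 21.9 CPM. The proteoglycan gene ogna (ENSDARG00000044132, chromosome 22, 10424921 to 10430198) had 81.6 ± 45.4 CPM in the Geminin-negative libraries and 1 count in all Geminin-positive libraries, a 3720-fold difference with an interval of 667 to 147000. Its row overlaps that of cenpp. The highest adjusted p over the alternatives was 0.1827 for col1a1a and 0.07225 for ogna. The bone matrix share of all counts was 20.1% ± 5.08 against 38.5% ± 7.3 (exact permutation p = 0.1). The mean log2 CPM of its members, here scaled by total counts without TMM, was lower by 0.54 in the Geminin-positive libraries. Scaling by library size alone shifted the median gene by -0.46. With TMM the mean log2 fold change of the measured members was -0.17. Among the genes with the highest mean CPM, col1a2 had 28144 ± 9680 against 124620 ± 53290 CPM (edgeR adjusted p = 0.06063), and col10a1a and hsp70.3 did not pass (adjusted p = 0.8119 and 0.9999). The 10 most abundant genes took 26.1% to 34.5% of the counts in the Geminin-negative and 43.0% to 53.3% in the Geminin-positive libraries.

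Osteoblast transcription factors were not called as a list (camera adjusted p = 0.2672), with 20 of 29 members negative and 0 passing over all genes. Adjusted over the list alone 2 rose, among them creb3l1, and 3 fell, among them twist2 and msx2b.

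The secretory pathway list was called higher (camera adjusted p = 0.0005487; adjusted p = 0.6012 with an estimated correlation), with 48 of 63 members positive and 0 passing over all genes. Its member kdelr2a had 804 ± 197 against 1669 ± 432 CPM. Ribosomal protein genes (camera adjusted p = 0.005773; adjusted p = 0.7644 with an estimated correlation) had 78 of 81 members positive, and respiratory chain genes (camera adjusted p = 0.02755; adjusted p = 0.7754 with an estimated correlation) had 47 of 63 positive, with 0 passing in either. The medians of these 3 lists were 0.43, 0.27 and 0.21. Under scaling by library size alone, which shifted the median gene by -0.46, they were -0.04, -0.19 and -0.28. There the camera direction stayed up for all 3 lists, but the calls were lost (camera adjusted p = 0.08005, 0.8898 and 0.9371). None of the 3 passed with fry (adjusted p = 0.1546, 0.3913 and 0.54). Without Geminin-negative replicate 1 all 3 calls were lost (camera adjusted p = 0.1224, 0.08052 and 0.9199). The ribosomal protein call was also lost without Geminin-positive replicate 1 (0.111), and the respiratory chain call without Geminin-positive replicates 2 and 3 (0.2812 and 0.05235). The respiratory chain median was 0.04 and 0.34 without Geminin-negative replicates 1 and 2, and 0.13 without Geminin-positive replicate 2. The ribosomal protein median was 0.13 without Geminin-negative replicate 3 and 0.09 without Geminin-positive replicate 1. The ribosomal protein share of counts was 4.32% ± 0.23 against 3.74% ± 0.903 (exact permutation p = 0.4).

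Leukocyte genes were lower in the Geminin-positive libraries. Of 35 measured members 34 had a negative log2 fold change, with a median of -4.004, and camera called the list (adjusted p = 5.743e-24; adjusted p = 0.04646 with an estimated correlation). Over all genes 6 members fell and 0 rose, and adjusted over the list alone 22 fell. The antigen presentation genes cd74a (ENSDARG00000009087) and cd74b (ENSDARG00000036628) fell from 1372 ± 223 to 70.5 ± 39.6 CPM and from 585 ± 88.8 to 36.5 ± 6.36 CPM (edgeR adjusted p = 0.01494 and 0.003131). The complement gene c1qc fell from 233 ± 102 to 5.65 ± 3.94 CPM. The actin regulator coro1a had 28.9 ± 15.7 CPM in the Geminin-negative libraries and 0 counts in the others, at least 439-fold lower. Leukocyte genes took 0.460% ± 0.125 of counts in the Geminin-negative and 0.0267% ± 0.00761 in the Geminin-positive libraries (exact permutation p = 0.1).

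Osteoclast genes were also lower. Of 11 measured members 10 were negative, with a median of -2.39, and the list was called (camera adjusted p = 6.706e-07; adjusted p = 0.04646 with an estimated correlation). Over all genes 2 fell, itgb3b (87.2 ± 11.6 to 8.02 ± 0.566 CPM, edgeR adjusted p = 0.007012) and the protease gene ctsk (260.2 ± 13.2 to 57.4 ± 17.9 CPM, edgeR adjusted p = 0.02714), and adjusted over the list alone 6 fell. Osteoclast genes took 0.166% ± 0.00269 of counts in the Geminin-negative and 0.0422% ± 0.00579 in the Geminin-positive libraries (exact permutation p = 0.1). With the members of both lists left out, an alternative chosen after seeing the data, 53 genes changed, 11 higher and 42 lower. Of the 78 genes called in the main analysis only 8 were members of these lists and 70 were not. All 53 were among those 70, so the other lost calls were not list members.

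Among other cell types, dermal fibroblast genes were called lower (camera adjusted p = 0.006879; adjusted p = 0.1443 with an estimated correlation), with 18 of 22 members negative and 0 passing over all genes. Adjusted over the list alone 5 fell and 2 rose, lum and pdgfrl. The call was lost without Geminin-negative replicate 1 (adjusted p = 0.05569) or Geminin-positive replicate 1 (0.07271). The nerve and Schwann cell list was called lower on 5 members (camera adjusted p = 0.01995; adjusted p = 0.2038 with an estimated correlation), of which pmp22a, a myelin protein gene, passed over all genes. It lost its call without each of the 6 libraries in turn (adjusted p from 0.0865 to 0.4874) and with no low-count filter (0.2136). Keratinocyte (22 of 30 negative, camera adjusted p = 0.09506), pigment cell (3 of 6 negative, 0.2672), erythrocyte (5 of 11 negative, 0.6621) and endothelium (5 of 10 negative, 0.5403) lists were not called, and muscle had 4 measured members and was not tested. The keratinocyte list was called lower with limma-voom (adjusted p = 0.02174) and without Geminin-negative replicate 1 (0.001343). The pigment cell list was called lower without Geminin-positive replicate 2 (0.03477) or 3 (0.04987). The groups did not overlap in the share of counts of 3 of these lists (exact permutation p = 0.1 each). Part of such a difference comes from the bone matrix share, 20.1% in the Geminin-negative and 38.5% in the Geminin-positive libraries, which lowers other shares. Scaling by library size alone shifted the median gene by -0.46. Nerve and Schwann cell genes took 0.0540% ± 0.00694 in the Geminin-negative and 0.0108% ± 0.00279 in the Geminin-positive libraries, pigment cell genes 0.0349% ± 0.00282 and 0.0113% ± 0.00232, and keratinocyte genes 1.21% ± 0.271 and 0.806% ± 0.0903. The nerve and Schwann cell share rested largely on pmp22a (214 ± 17.2 against 73.1 ± 10.4 CPM) and pmp22b (200 ± 39.3 against 32.8 ± 20.9 CPM). It was therefore not shown to measure nerve or Schwann cell content. The groups overlapped in the shares of dermal fibroblast (0.764% ± 0.118 and 0.723% ± 0.145, exact permutation p = 0.8), endothelium (0.0148% ± 0.00409 and 0.0179% ± 0.00669, 0.7), erythrocyte (0.00867% ± 0.00675 and 0.00812% ± 0.00162, 0.9) and muscle genes (0.00203% ± 0.00129 and 0.000915% ± 0.000401, 0.4). In the pigment cell list tspan36 passed over all genes, falling from 176 ± 8.27 to 14.7 ± 8.97 CPM. It had the most counts of that list, and the pigment cell share rested largely on it. That share was therefore not shown to measure pigment cell content.

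**Figure D3:**
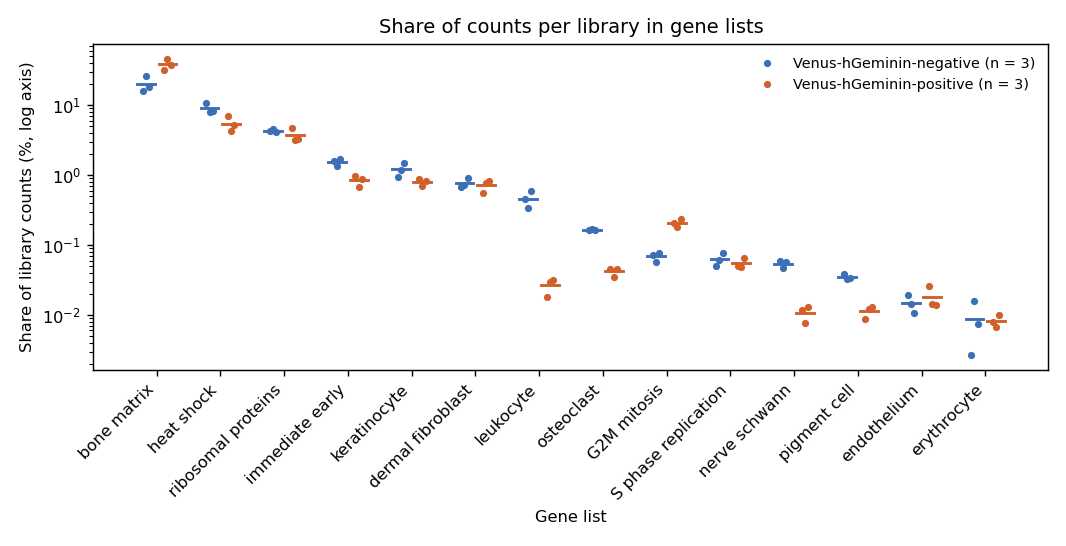
Each point is the share of 1 library's counts (percent, log axis) in the genes of a list, and bars are group means over 3 libraries. Leukocyte shares were 0.338% to 0.588% in the Geminin-negative and 0.0180% to 0.0321% in the Geminin-positive libraries.

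Other large decreases were il4i1, with 32.7 ± 19.2 CPM against 3 counts in all Geminin-positive libraries (496-fold, interval 170 to 2410), and tnn, with 22.6 ± 13.2 CPM against 1 count (1030-fold, interval 185 to 40600). With 0 counts in the Geminin-positive libraries, plaua was at least 464-fold, scara3 at least 434-fold, mmp13b at least 369-fold, tafa1a at least 362-fold, adgrg3 at least 340-fold and ebf1b at least 325-fold lower. The gene zmp:0000001268 fell from 1496 ± 152 to 15.5 ± 11.03 CPM. One copy of the MFAP4 cluster also fell (log2 fold change -7.23). Of these decreases only that of zmp:0000001268 kept its call in all 17 alternative fits. The highest adjusted p over those fits was 0.3623, for the MFAP4 copy, which kept its call in 8 of 17. The folds and bounds cover counting error only, not the spread between libraries. The row of the MFAP4 copy overlaps those of 4 other genes. The rows of pfn1, itgbl1, cd74b, tnn, col5a1, RRM2, mmp13b, ebf1b, myo18aa, col1a1a, col1a2, ncapd2, pdgfrl, jag1b, mcm3 and hsp70.3 also overlap other gene rows, so their counts are less certain.

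The Erk feedback and ETS list was not called (camera adjusted p = 0.357), with 14 of 19 members negative and 0 passing over all genes. The Erk phosphatase gene dusp6 had 24.1 ± 9.84 CPM in the Geminin-negative and 25.1 ± 12.3 CPM in the Geminin-positive libraries, and spry4, a feedback inhibitor, 21.8 ± 4.80 and 6.08 ± 3.70 CPM (edgeR adjusted p = 0.9999 and 0.3754). Adjusted over the list alone 1 member, dusp2, was lower, with 97.7 ± 35.2 against 24.96 ± 12.27 CPM. Receptor tyrosine kinase ligands and receptors were not called (camera adjusted p = 0.0874, 15 of 19 negative). Immediate early genes were called lower (camera adjusted p = 0.02755; adjusted p = 0.2766 with an estimated correlation), with 23 of 28 negative and 0 passing. The list lost its call without Geminin-negative replicates 1, 2 or 3 (adjusted p = 0.087, 0.1117 and 0.0537) and Geminin-positive replicates 1 or 2 (0.1455 and 0.1112). It was also lost with no low-count filter (0.05272), the length correction (0.06136) and fry (0.06388). Its share was 1.54% ± 0.187 against 0.847% ± 0.145 (exact permutation p = 0.1), and that of heat shock genes, a list not called (camera adjusted p = 0.09506, 17 of 21 negative), was 8.99% ± 1.62 against 5.44% ± 1.4 (exact permutation p = 0.1). The larger bone matrix share of the Geminin-positive libraries contributes to both differences in share. The heat shock list was called lower with limma-voom (adjusted p = 0.003184), library size only (0.01348) and fry (0.01248). Genes of both lists are known to respond to tissue dissociation.

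Notch pathway genes were called lower (camera adjusted p = 0.002844; adjusted p = 0.1443 with an estimated correlation), with 11 of 13 negative and 0 passing over all genes. Adjusted over the list alone 4 fell: lfng, heyl, jag1b and mfng, the last with 0 counts in the Geminin-positive libraries. Cytoskeleton genes were called lower (camera adjusted p = 0.0133; adjusted p = 0.1443 with an estimated correlation), with 35 of 45 negative. Over all genes 1 fell, the actin-binding profilin gene pfn1 (854 ± 284 to 107 ± 9.21 CPM, edgeR adjusted p = 0.01057), and adjusted over the list alone 6 fell. The call was lost without Geminin-negative replicate 3 (adjusted p = 0.05206) or Geminin-positive replicate 1 (0.111). The lists of hedgehog (camera adjusted p = 0.4699), Wnt (0.105), Bmp (0.9749), p53 and apoptosis (0.4255), glycolysis (0.8219) and ribosome biogenesis genes (0.2104) were not called. The ribosome biogenesis list was called higher without Geminin-negative replicate 3 (adjusted p = 0.02414), and the Wnt list lower with fry (0.04322). The median and the camera direction differed in sign for the bone matrix, endothelium, Bmp and p53 lists. Of the p53 and apoptosis list isg15, an interferon-induced gene, fell over all genes.

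**Figure D4:**
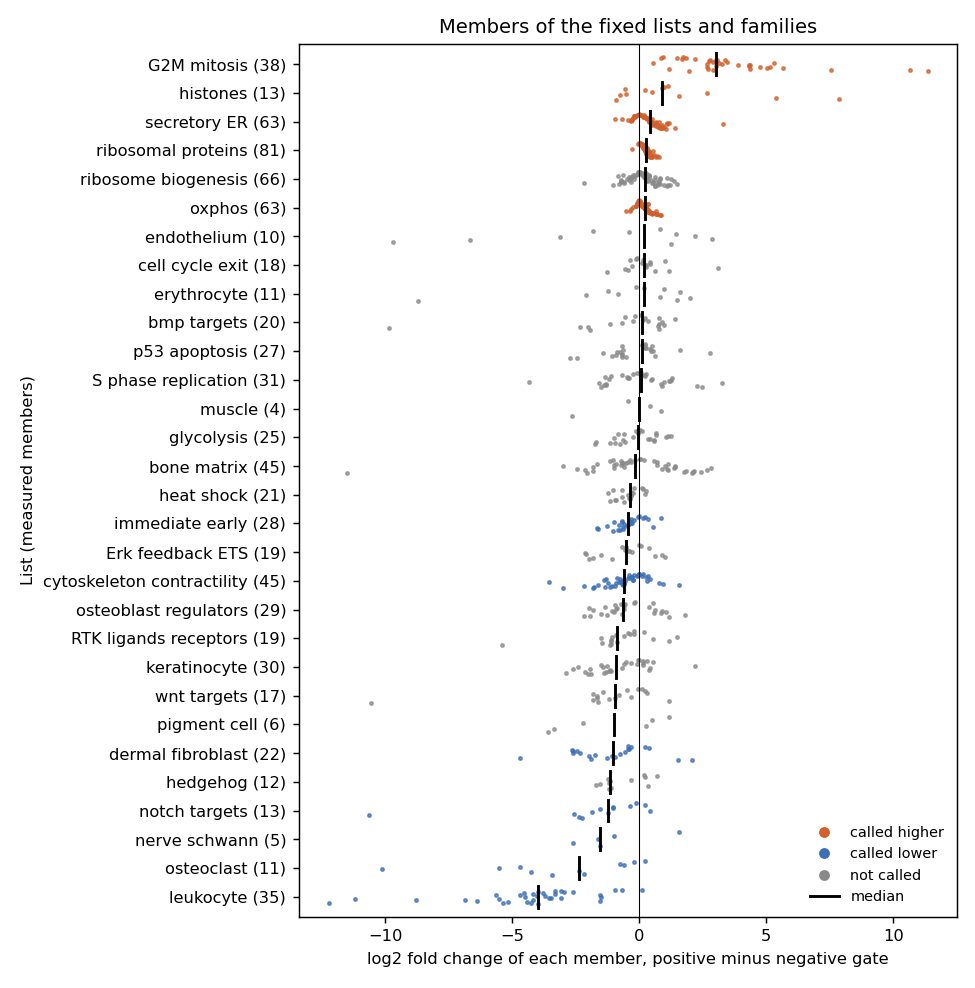
Each point is the log2 fold change of 1 measured member, Geminin-positive minus Geminin-negative, in each list or family (measured members in brackets), the black bar is the median, and colours mark lists called by camera. G2/M genes lie highest, with a median of 3.02, and leukocyte genes lowest, with a median of -4.004. Scaling by library size alone shifts the median gene by -0.46. Under it the secretory, ribosomal protein and respiratory chain medians are negative, while their camera direction stays up.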

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

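The alternative without leukocyte and osteoclast list members was chosen only after the result was seen. The count of changed genes, 78, stayed within 1.5 times under the RLE and upper-quartile scalings, the stricter filter, limma-voom, the length correction with and without the block, and the fit without robust dispersion. It was 185 with library size only, 557 with no low-count filter, 626 with DESeq2 (594 with an absolute log2 fold change of at least 1) and 7 at an adjusted p under 0.01. All 7 were lower in the Geminin-positive libraries. With a library left out the count ranged from 22 to 96. The cause was not tested. In the simulation 35.7% of the calls by DESeq2 and 6.76% of those with no low-count filter were false, against 2.92% in the main analysis. The replicate block gave 134 genes (131 with an absolute log2 fold change of at least 1), of which 61 were among the 78. Of the 134 genes 47 were higher, and with the length correction and block 36 of 108 were. The block gave a G2/M median of 4.83, or 4.97 with the length correction. The numbers were not shown to pair the libraries: the correlations of deviations for the same number were 0.18, 0.06 and 0.04, and not every library correlated best with its own number. The number of called lists, 12, was 3 with an estimated correlation and 6 to 11 with a library left out. Under the alternatives, the 12 called lists kept the call in 157 values, lost it with the direction kept in 44 and lost it with the direction turned in 2, and 5 of the other 17 lists gained one in 9 values. The histone call was lost with the block (adjusted p = 0.05637) and with the length correction and block (0.05197), and the block changed no other list call. The respiratory chain list turned direction without Geminin-negative replicate 1 (adjusted p = 0.9199, against 0.001215 without Geminin-negative replicate 3), and the histone list turned under the stricter filter (adjusted p = 0.867). Among uncalled lists, the Bmp direction turned with upper-quartile scaling (adjusted p = 0.9833), the stricter filter (0.7768), limma-voom (0.6929), the length correction (0.9485) and the length correction with the block (0.9129), and the erythrocyte direction turned with fry (0.7922). The S phase, bone matrix, Bmp and erythrocyte directions turned without Geminin-negative replicate 1, Bmp also without Geminin-negative replicate 2 or Geminin-positive replicate 3, glycolysis without Geminin-negative replicate 3, and pigment cell without Geminin-positive replicate 1. Over all 6 fits that left a library out, turned or not, adjusted p ranged from 0.1295 to 0.7889 for S phase, 0.3931 to 0.9364 for bone matrix, 0.3813 to 0.9978 for glycolysis, 0.6917 to 0.9978 for Bmp, 0.1933 to 0.7889 for erythrocyte and 0.03477 to 0.9559 for pigment cell.

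Of the 34 called genes among those named, 28 lost the call in at least 1 of the 17 alternative fits, and none turned direction. The threshold of 0.01 is not among these fits. At that threshold gmnn, pfn1 and cd74a lost the call too (edgeR adjusted p = 0.01057, 0.01057 and 0.01494). Log2 fold changes of uncalled genes turned sign as follows. With library size only they were -0.36 for dusp6, -0.0117 for rps12, -0.15 for sufu, -0.22 for paics and -0.11 for neb. For dusp6 it was -0.0230 with the block and -0.0256 with the length correction and block. For desma it was 0.45 with limma-voom. With a library left out, dusp6 ranged from -0.26 to 0.42, neb from -0.24 to 2.58, desma from -1.09 to 0.45 and tnnt3a from -0.0751 to 1.46. Some differences in share of counts turned sign as the difference in mean log2 CPM of the members, scaled by total counts without TMM. These log2 values, which include the shift from that scaling, were -0.54 for bone matrix, 0.16 for histones and -0.30 for endothelium. With a library left out, in percentage points, histones ranged from -0.0352 to 0.0157, erythrocyte from -0.00355 to 0.0031, endothelium from -0.000804 to 0.00515 and dermal fibroblast from -0.0977 to 0.0409. The exact test cannot go below 0.1 for these shares, or 0.25 when paired, so it says nothing of their stability. The mitochondrial alternatives gave no value, as the tables hold 0 such rows.

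The real grouping gave 78 genes and 12 lists, and the highest other of the 10 splits of the 6 libraries gave 0 genes and 5 lists. In both cases 1 split, the real one, reached the real value, and 10 splits are too few for a share under 0.05. Depth limits genes of low level: 3 counts correspond to 0.0824 to 0.216 CPM per library.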

Other observations

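The tests of the lysosome list, of abundant leukocyte genes, of swapped libraries and of the gmnn level were chosen only after the result was seen. Genes of the lysosome, the organelle of macromolecule breakdown, were lower in the Geminin-positive libraries in a list written after the called genes were seen. Of 57 measured members 46 had a negative log2 fold change, with a median of -0.9965. Over all genes 5 fell, and adjusted over the list alone 17 did. The 5 were psap (log2 fold change -2.63), cd63 (-1.96), lgmn (-2.46), naga (-3.64) and ctsd (-2.01), all chosen after their values were seen. With the called genes and 2 members of the leukocyte or osteoclast lists left out, 40 of the other 50 were negative and camera with an estimated correlation gave p = 0.02452. The hypothesis is a lower level across lysosomal genes in the Geminin-positive gate. Leukocytes and osteoclasts also express such genes, so a difference in those cells stays open as their source.

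Leukocyte genes were lower in the Geminin-positive libraries although both gates required mCherry driven by osterix sequence. If a lower share of osteoblasts raised every other cell type alike, the other lists would have medians near the leukocyte median. The 6 lists named for this test (keratinocyte, endothelium, dermal fibroblast, pigment cell, nerve and Schwann cell, and muscle with 4 members) had medians more than 1 log2 unit above the leukocyte median, with 95% intervals of the difference above 0. Of the 2 lists outside the test, the erythrocyte median lay 4.18 above it (interval 2.64 to 5.49), and the osteoclast median was not separated from it (1.62, interval -0.89 to 3.57). Outside muscle and endothelium, these medians argue against an equal rise across those lists. They do not exclude a lower share of osteoblasts in the Geminin-negative libraries. The 4 muscle genes had group means of at most 4.3 CPM, and a list of cells that are nearly absent cannot show a rise. The endothelium list was split, with 5 of 10 members negative. Its members robo4 and tek had log2 fold changes of -9.70 and -6.66, and sox18 had 1.26. The test assumes that osteoblasts do not express the listed genes, and its intervals treat genes as independent. In the fibroblast list lum and pdgfrl were higher in the Geminin-positive libraries, while 18 of 22 members were negative. The bone matrix share was 20.1% in the Geminin-negative and 38.5% in the Geminin-positive libraries. A single library was not the cause, as the leukocyte list was called lower in all 6 fits that left 1 out. Their camera adjusted p, at the preset correlation of 0.01, ranged from 1.288e-23 to 2.834e-15. The estimated correlation was not used in these fits, and with all 6 libraries it gave a camera adjusted p of 0.04646. Leukocytes in the Geminin-negative gate and leukocyte genes expressed by the osteoblasts themselves both stay open and cannot be told apart. Of the 10 most abundant list members 10 were lower by more than 1 log2 unit, led by cd74a at 1372 and cd74b at 585 CPM, but either explanation gives that value.

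The Erk feedback list was not higher in the libraries labelled high Erk. Libraries swapped between the groups are argued against by the G2/M list, whose median log2 fold change was 3.015 in the Geminin-positive libraries, and by gmnn. Whether the Erk wording of the labels or that of the series' design text describes these cells stays open. The list's adjusted p of 0.357 does not show that feedback genes were equal.

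The gene gmnn had a higher CPM than every other measured S phase or G2/M list member in 6 of 6 libraries, by 3.08 to 6.75 times in the Geminin-negative and 9.42 to 16 times in the Geminin-positive libraries. Reads of the reporter transgene counted at gmnn, reads from the overlapping ripor2 row and a high level of the endogenous transcript cannot be told apart. Each could give that rank, and gene counts do not separate them. The reporter's geminin sequence is human, so its reads would have to align to the zebrafish gene, which was not tested. Without gmnn the G2/M share of counts was 0.0218% ± 0.00556 in the Geminin-negative and 0.0746% ± 0.0244 in the Geminin-positive libraries (exact permutation p = 0.1, the smallest possible).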
